A study of Mus musculus with 2 samples.

How the data were processed

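The data are STARR-seq output libraries from activated mouse Th2 cells, 2 libraries that the labels name as biological replicates 1 and 2 of 1 group. Per the labels, the nucleic acid starting quantity was 30 ug, the size range 200 to 400, RNA was extracted with a Qiagen method, and an input experiment is named as a possible control. That input experiment is not analysed here. Both libraries carry the same donor record, so nothing in the labels says whether they came from separate animals.

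The authors deposited 1 element table for the series, made from the alignments of both output libraries on the mm10 assembly, per the deposited text lists of files. The aligner, the caller of the elements, the test behind the p-values and their versions are not given in the sources used here. The table has no header. The authors' signed log2 fold change of each element is in the signal column of the narrowPeak layout. Its base and what it is relative to are not given in the sources used here. Base 2 and output over input are assumptions, and a change of base would rescale every fold while leaving the sign, the order and the counts by sign alone as they are. Counts at a cut on the log2 fold would then stand for a cut at another fold. The authors' deposited p-value and q-value are linear, not -log10 values. The last column is the width of the element, equal in all 18431 elements to end minus start plus 1, so the deposited starts count from 1. Widths ran from 50 to 2125 bp on a grid of 25 bp. The product of q-value and rank divided by p-value gave the whole number 114722 for 81.8% of elements, within a relative tolerance of 1e-06, as Benjamini-Hochberg adjustment over that many regions would.

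The table holds no read counts, so the depth of each library and of each element is unknown, and no interval, floor or filter on depth could be applied to single elements. More deeply covered elements have more precise folds, and this cannot be seen in the table. Binomial and Fisher intervals cover counting error over elements only. Neighbouring elements and copies of 1 sequence are not independent, so p-values across elements are smaller than those of independent observations would be.

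Elements on the 19 autosomes, X and Y (18414) entered all comparisons of sequence and genes, with the GRCm38 p6 genome and GENCODE M21 annotation, the same build as the table. The 17 elements on other scaffolds entered the counts and the analysis of width alone. The class of an element was set by its midpoint, as promoter (within 1000 bp of an annotated start of a protein-coding transcript), then exon, then intron, then intergenic. Classes were compared with Fisher's exact test (two-sided) and Benjamini-Hochberg adjustment, between positive and negative elements and against same-width regions 5 kb to each side that overlap no element. GC content and the CpG ratio were compared by medians with 100000 permutations. A list of 38 consensus sites, fixed before the data were examined, was searched on both strands. Each site was tested by Fisher's exact test and by a logistic model with length, GC content and CpG density, and a site was called when both passed an adjusted threshold of 0.05 in the same direction. Elements and 1 flank each were compared by the exact McNemar test.

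The 17 gene lists, also fixed before the data were examined, cover Th2, Th1, Th17 and regulatory T cells, T-cell receptor and costimulation, T-cell activation, interleukin-2 and STAT5 targets, type I interferon response, naive and memory T cells, p53 targets, ribosomal proteins, cell cycle, and B-cell, myeloid, neuronal, liver and muscle markers. The share of a list's genes with an element within 50 kb of the gene start was compared with 10000 random sets of protein-coding genes, matched on deciles of the number of gene starts within 500 kb, and adjusted over 34 tests (17 lists in both directions). The smallest p the random sets can give is 0.0002 before adjustment. The numbers of positive and negative elements near each list were also set against all other elements by Fisher's exact test, adjusted over the 17 lists. The sites of 7 pairs of list and factor were compared in the same way after the data were seen. Of the 24 interferon genes 23 matched the annotation, and every gene of the other lists matched. A few genes stand in more than 1 list, such as Junb and Il2ra, and neighbouring genes share elements, such as Il4 with Il13 and Il3 with Csf2. Clustering was tested with 1000 reshufflings of direction within each chromosome, and width against absolute fold with Spearman's rho and 100000 permutations.

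Named elements follow a rule fixed before the data were examined. It takes the 12 elements per direction with the lowest q-value (ties by p-value, then absolute fold), the 5 per direction with the largest absolute fold, the 3 genes per direction with the most elements within 50 kb, and up to 4 genes per list by the lowest q-value of an element within 50 kb. The rule also asked for an input value at or above the median for the largest folds, which this table does not carry, so the largest folds are named without a depth filter. Some list members are left unnamed for length, elements of chromosome 18 are not named, and a few other genes the rule takes are not reported here.

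Other matches of each element in the genome, including the mitochondrial genome, were found with minimap2 2.31 and counted as near-identical at an identity of at least 95% over at least 90% of the element, widened to 200 bp where it was narrower. Related elements were found with BLAST 2.17.0 as alignments of at least 100 bp, 75% identity and 50% of the shorter element, with every positive element of at least 200 bp searched against all others. Repeat-masked sequence is the lower-case part of the genome sequence used, and repeats that this masking misses are not counted. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, pysam 0.24.0 and matplotlib 3.10.9.

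The tests were run on simulated data first. Of simulated consensus sites with a true odds ratio of 2, all 100 were called, none of 100 sites that followed GC content alone was, and 0.75% of 400 unrelated sites were. The simulated direction followed GC content and CpG density in the linear form that the logistic model assumes. It therefore cannot show how well the model handles a trend of another form. Of 200 random gene lists 5.5% had a permutation p under 0.05, and all 100 lists of 20 genes with 18 members near an element did. The simulated genes had no positions and shared no elements. This therefore cannot show how the list test behaves where neighbouring genes of a list share an element. The common odds ratio within GC bins had a median of 1.01 where the true value was 1 and 3.05 where it was 3.

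Alternatives set beforehand were an absolute log2 fold of at least 1, 1 element per cluster of elements within 5 kb, autosomes alone, promoter windows of 500 and 2000 bp, class by any overlap, the central 200 bp for consensus sites, sets matched on GC content and length (2215 elements per direction), list windows of 10 and 100 kb, the nearest start alone, and clustering within 2 and 50 kb. A q-value below 0.001, lists thinned to 1 gene per 100 kb, elements with no other near-identical match and elements outside promoters were added after seeing the data. Alternatives used 10000 permutations for medians and correlations.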

Results

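STARR-seq, an assay in which genomic DNA fragments are placed in a plasmid inside a transcription unit, so that the RNA of a fragment reports its own activity, was carried out in activated T-helper 2 (Th2) cells of C57BL/6NJ mice. Th2 cells are the helper T cells that make the cytokines IL-4, IL-5 and IL-13. Per the labels, the primary cells received anti-CD3e at 0.25 ug/mL and anti-CD28 at 1 ug/mL for 3 days, which stimulate the T-cell receptor and its costimulator, together with anti-interferon-gamma at 2 ug/mL and interleukin-2 for 4 days, and interleukin-4. The plasmid pool was introduced by transient transfection. The study holds 1 group of 2 output libraries, labelled as biological replicates 1 and 2 with the same donor record, and no other cell state or treatment. The comparisons its design allows are therefore among genomic elements, and ask which sequences raised or lowered reporter RNA in these cells.

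The file analysed here is the authors' deposited table of elements, made from both libraries together, with a signed log fold, a p-value and a q-value for each element and no value per library. No spread between the 2 libraries can be given, the read depth behind an element is unknown, and each fold stands without an error of its own. Folds, p-values and q-values of single elements are the authors'. The base of the logarithm and the direction of the ratio are not given in the sources used here. They are read as log2 and as RNA output over input DNA, and elements are called positive or negative by the sign of the fold alone.

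The table held 18431 elements, of which 13183 had a positive fold and 5248 a negative fold. Positive elements made up 71.5% of the total (exact 95% binomial interval 70.9 to 72.2, counting error only). Every q-value was below 0.01, and the relation of p to q placed the elements among 114722 tested regions, so that 16.1% of the regions were kept. The median fold was 2.30 in the positive elements (log2 1.20) and 2.35 in the opposite direction in the negative ones (log2 -1.23). Large folds were more frequent on the positive side, where 900 elements had an absolute log2 fold of at least 3, against 101 negative elements. Positive elements were narrower, with a median width of 450 bp against 750 bp. Wider positive elements had smaller folds (Spearman's rho -0.18 across elements, permutation p = 1e-05) and wider negative elements had larger ones (rho 0.17, permutation p = 1e-05), both at the smallest p that the permutations can give. Elements are not independent replicates. Both correlations use only elements that passed the q-value cut, which can itself tie fold to width, and the permutations do not allow for this.

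The 12 positive elements with the lowest q-values shared the value 1.6e-12 in the authors' deposited table, and 9 of them lay outside genes and promoters. Among them were a pair of promoter elements of antiviral TRIM genes on chromosome 7. The element at Trim5 (mm10 chromosome 7, 104287576 to 104288300) was 156 bp from an annotated start and had a log2 fold of 5.18, and the one at Trim12a (chromosome 7, 104314676 to 104315600) was 317 bp from one and had a log2 fold of 4.69. Both carried an interferon-stimulated response element (ISRE) consensus. An intergenic element 50884 bp from the start of Dusp4, which encodes a MAP kinase phosphatase (chromosome 8, 34756226 to 34756600), carried AP-1 and GATA consensus sites and had a log2 fold of 3.99. The other elements named by this rule were nearest to Sfi1 (log2 4.81), Arl14ep (5.23), Hfe2 (5.85), Cnot2 (4.88), Thsd7b (5.08, in an intron), Gm11114 (4.27), Mdfic (5.26), Eapp (5.87) and Col19a1 (6.03). The Eapp and Col19a1 elements each had 1 other near-identical match in the genome, which for the Col19a1 element (chromosome 1, 24612926 to 24613550) was in the mitochondrial genome. Relatives of lower identity are not counted here. The Hfe2 element (70.3% repeat-masked) belongs to a group of 14 related elements, and the Cnot2 element (71.6% repeat-masked) carried all of its consensus sites. The Arl14ep, Thsd7b and Mdfic elements also had a set of consensus sites in common. The nearest start is given as a landmark, and no link between an element and that gene was measured.

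Of the 12 negative elements with the lowest q-values, 11 lay at promoters. The lowest q-value, 9.98e-11, belonged to a 75 bp element 358 bp from a start of Ptms, which encodes parathymosin (chromosome 6, 124917551 to 124917625, log2 -4.25). The promoter of Dnmt3a, a DNA methyltransferase, held a 50 bp element with a log2 fold of -2.80 (chromosome 12, 3806651 to 3806700). Pbrm1, a subunit of a chromatin remodelling complex, had a promoter element at -3.78 and Slc30a1, a zinc exporter, one at -3.49. The remaining promoters were those of Pknox1 (-3.66), Lcor (-3.59), Shf (-4.05), Gdf11 (-3.65), Farp1 (-3.36), Smco4 (-3.55) and Cdon (-2.91), and the element outside a promoter lay in an intron of Mllt10 (-3.33). GC content ranged from 63.7% at Gdf11 to 80% at Dnmt3a.

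The largest positive folds in the authors' deposited table were at elements nearest to Zfp53 (chromosome 17, 21477701 to 21478600, log2 9.04), Gm8797 (8.29), G530012D18Rik (8.14), Gvin1 (7.97) and Vmn2r41 (7.91). The last 3 of these had 3, 2 and 7 other near-identical matches in the genome, and how reads shared with those matches were counted is not given in the sources used here. Among the negative elements the most extreme folds were nearest to Epm2a (-8.58), Slc4a7 (-4.93), Zdhhc18 (-4.64), Gnao1 (-4.48) and Rai2 (-4.47), and 4 of these 5 were promoter elements. The genes with the most positive elements within 50 kb of their start were in the histone cluster on chromosome 13, where Hist1h1d, Hist1h2ad and Hist1h2ae each had 10. For negative elements the highest number was 6, at Clcf1 on chromosome 19 and Cops7a on chromosome 6 among others.

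Positive and negative elements occupied different parts of the genome. Promoters, here within 1000 bp of an annotated start of a protein-coding transcript, held 73.8% of the negative elements (3870 of 5244 on assembled chromosomes) and 13.6% of the positive ones (1787 of 13170). Introns held 39.6% of the positive and 11.3% of the negative elements, and intergenic sequence 44.3% and 12.1%. The odds ratio of a promoter position, positive against negative, was 0.0557 (exact 95% interval 0.0515 to 0.0604), with values of 5.17 for introns and 5.77 for intergenic sequence. The p-values of these 3 exact tests (Fisher's, two-sided) were too small for the software to represent. The share in exons did not differ past the threshold (2.46% against 2.80%, Fisher's exact test, adjusted p = 0.196), and that result turned with the definition of the class, from an odds ratio of 0.558 with promoters of 500 bp to 1.28 when any overlap of the element was counted.

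Seen from the gene side, 31.6% of the promoter elements were positive (exact 95% interval 30.4 to 32.8), against 89.8% of intronic and 90.2% of intergenic elements. Both kinds of element were more frequent at promoters than their own flanking regions 5 kb away, of which 3.67% (positive) and 4.39% (negative) lay at promoters. For the positive elements this gave an odds ratio of 4.12 (Fisher's exact test, adjusted p = 3.72e-268) and for the negative ones 61.4. At a q-value below 0.001 these were 3.74 and 152, and the odds ratios of positive against negative elements were 0.0207 for promoters, 12.8 for introns and 13.2 for intergenic sequence. The last promoter value was 0.0351 at an absolute log2 fold of at least 1. Whether the flanking regions were among the tested regions is not known here, so contrasts with flanks cannot tell activity from which DNA was tested.

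**Figure D1:**
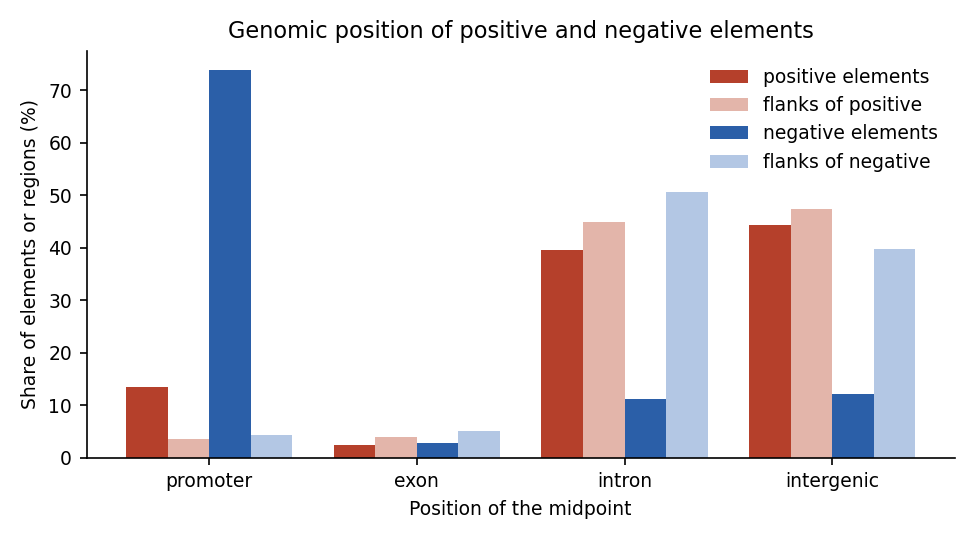
Share of elements or flanking regions (%, vertical axis) with their midpoint in each annotation class, for positive elements, negative elements and the flanking regions of each. Promoters hold 73.8% of the negative and 13.6% of the positive elements, against 3.67% and 4.39% of the flanks of positive and negative elements.

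Base composition separated the same sets. The median GC content was 47.5% in positive and 66.3% in negative elements, a difference of -18.8 points (permutation p = 1e-05, the smallest possible), and 44% and 44.9% in their flanks. The median ratio of observed to expected CpG was 0.231 in positive and 0.787 in negative elements (permutation p = 1e-05). The medians were 67.8% in negative and 57.6% in positive promoter elements, 68% and 47.3% in exonic, 48.7% and 46.5% in intronic, and 50.6% and 46.8% in intergenic ones. Above a GC content of 50%, the share of negative elements rose with GC content both at promoters and elsewhere. It was 9.21% at promoters and 7.21% elsewhere below a GC content of 45%, and 93.5% (2943 elements) and 81.8% (302 elements) at 65% or more.

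**Figure D2:**
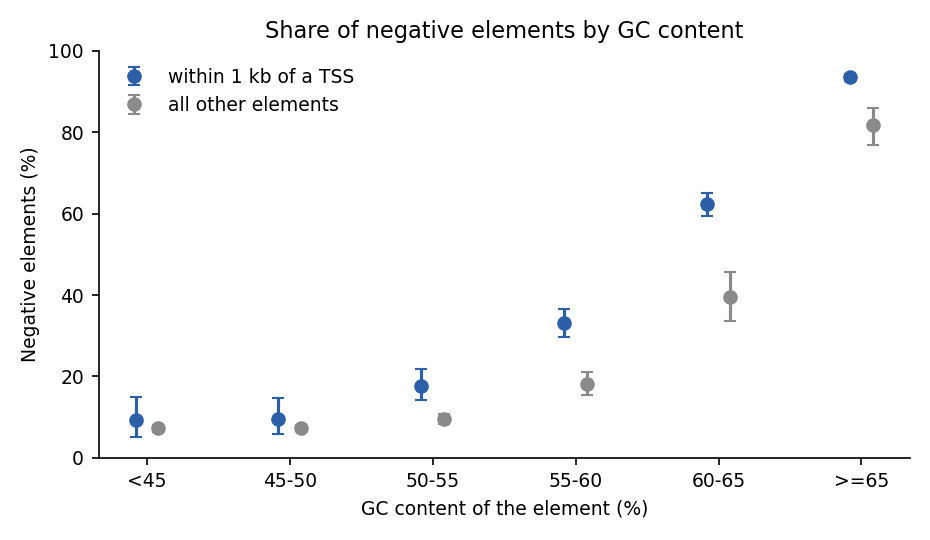
Percentage of elements with a negative fold (vertical axis) by GC content of the element (horizontal axis, percent), for promoter elements and for all others, with exact 95% intervals. The share rises from 9.21% to 93.5% at promoters and from 7.21% to 81.8% elsewhere.

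A fixed list of 38 consensus sites was searched in all elements. Of these, 9 sites were more frequent in positive elements, both by Fisher's exact test and in a logistic model that held length, GC content and CpG density. AP-1, the FOS and JUN dimer induced by T-cell receptor signals, had the most frequent of these sites, in 35.2% of positive and 9.95% of negative elements (adjusted odds ratio 1.80, 95% interval 1.59 to 2.03). The STAT site, bound by the STAT proteins that act downstream of cytokine receptors, was in 23.5% and 10.6% (1.77), and the STAT6 spacing, the one used downstream of interleukin-4, in 14.2% and 8.96% (1.34). The ISRE of interferon regulatory factors was in 15.6% and 4.08% (2.58, 2.15 to 3.10). Sites of NF-kB (1.73), MAF (1.99) and TEAD (1.21) were also higher in positive elements. The MAF consensus contains that of AP-1, so each MAF site was counted as an AP-1 site too, and the STAT and STAT6 sites belong to the same factor family.

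The strongest adjusted contrasts were at rarer sites. The consensus of p53, the DNA damage response factor, was in 237 positive and 6 negative elements (Fisher's exact test, adjusted p = 1.87e-26, adjusted odds ratio 6.31, interval 2.66 to 14.9). The median log2 fold of positive elements with this site was 2.60, against 1.19 without it. Of the 237 positive elements with the p53 consensus, 83 belong to 1 group related in sequence. Both tests counted them as separate, and the p-value and interval do not allow for this. The cyclic AMP response element (CRE) was in 3.01% of positive and 2.15% of negative elements (Fisher's exact test, adjusted p = 0.00191). Its odds ratio was 1.41 unadjusted and 4.55 (3.47 to 5.96) adjusted. The model takes the trends with GC content and CpG density as linear. Outside promoters, 7.21% of elements were negative below a GC content of 45%, 7.27% from 45% to under 50%, and 81.8% at 65% or more. How much of the adjusted value comes from the linear form was not tested. Negative elements had more SP/KLF sites, in 32.1% against 4.58% of positive elements (adjusted odds ratio 0.770, 0.673 to 0.882), and more CTCF sites, in 3.30% against 1.45% (0.267, 0.207 to 0.345).

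GATA sites, bound by the Th2 regulator GATA3, were in 19.4% of positive and 10.3% of negative elements, and the adjusted odds ratio of 1.04 (0.909 to 1.18) did not pass the threshold. Sites of RUNX (0.983), NFAT (0.926) and TCF7/LEF1 (1.02) likewise lost their difference with the covariates in place. ETS, YY1 and NFY sites were less frequent in positive elements by Fisher's exact test, and had adjusted odds ratios above 1 (1.86, 4.24 and 1.51). The calls of TEAD, SP/KLF, MAF and NF-kB were lost under at least 1 alternative setting, and the direction of SP/KLF turned outside promoters (adjusted odds ratio 1.16). At a q-value below 0.001 the CRE, STAT6 and CTCF calls were also lost, with CTCF at 0.623. The p53 odds ratio kept its call but not its size, at 11.1 in sets matched on GC content and length, 11.8 in the central 200 bp, 17.7 at a q-value below 0.001 and 21.8 outside promoters. In the central 200 bp, CRE was at 7.18, ISRE at 4.30 and MAF at 3.41, and CRE was at 7.97 outside promoters and MAF at 3.34 at a q-value below 0.001.

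**Figure D3:**
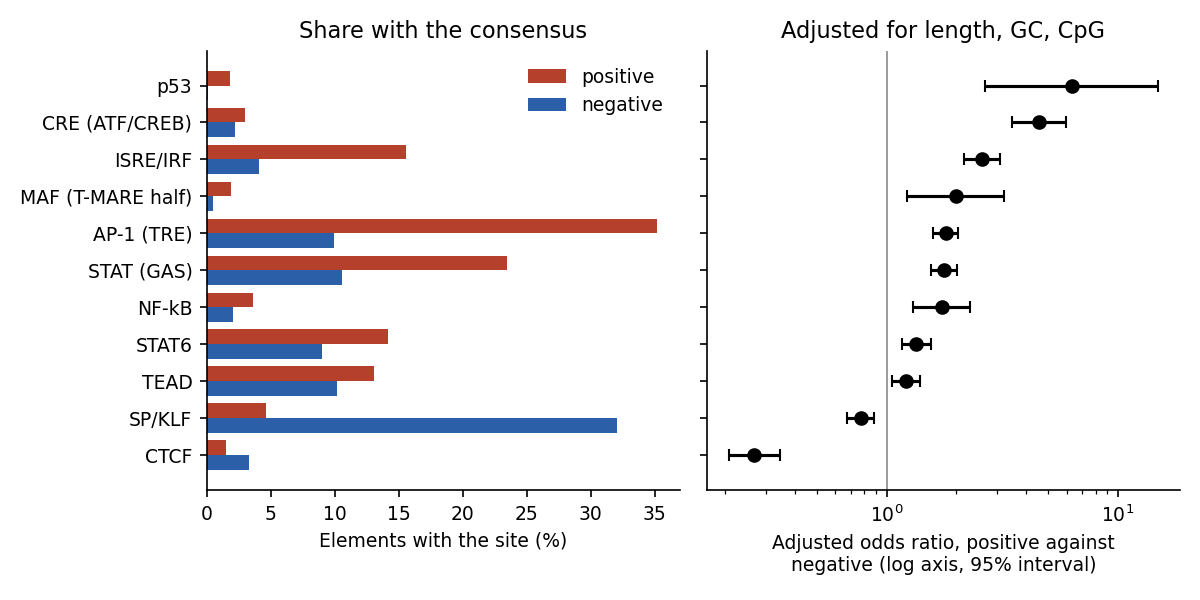
Left, percentage of positive and negative elements with each of the 11 consensus sites called in both tests; right, odds ratio from the logistic model (log axis) with its 95% interval, where values above 1 mean more frequent in positive elements. The adjusted odds ratio runs from 0.267 for CTCF to 6.31 for p53.

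Against flanking sequence, AP-1 showed the widest gap in the positive elements, at 35.2% of elements and 7.54% of flanks. CRE sites were in 3.01% of positive elements and 0.281% of their flanks (exact McNemar test, adjusted p = 1.37e-78), NF-kB sites in 3.56% and 0.911% (exact McNemar test, adjusted p = 1.99e-50), and p53 sites in 1.80% and 0.235% (exact McNemar test, adjusted p = 3.76e-40). The composite BATF and IRF site (AICE) was in 0.896% and 0.152% (exact McNemar test, adjusted p = 9.92e-18). GATA sites were less frequent in positive elements than in the flanks, 19.4% against 24.6% (exact McNemar test, adjusted p = 4.00e-26), and NFAT sites 5.93% against 7.40%. In total 24 of the 38 sites were higher and 5 lower in positive elements than in flanks, and 13 were higher and 19 lower in negative elements. These tests do not correct for the base composition of the elements. Whether the flanks were among the tested regions is not known here, so the gaps cannot tell activity from which DNA was tested.

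Examples of sites in their sequence context come from the elements with the most extreme fold, among those with no other near-identical match in the genome, and were chosen after the values were seen. The lack of such a match does not make them free of repeats. The p53 example was 76.4% repeat-masked and the element near Hfe2 70.3%, against 6.4% for the AP-1 and 4.1% for the CTCF example. The p53 example was an intergenic element 267375 bp from the start of Chl1 (chromosome 6, 103965001 to 103965250, log2 5.58), with the sequence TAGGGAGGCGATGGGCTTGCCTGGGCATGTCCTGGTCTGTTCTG at 103965045 to 103965088. The AP-1 example was an intergenic element 50337 bp from Ugt2b34 (chromosome 5, 86856476 to 86856725, log2 4.79), which reads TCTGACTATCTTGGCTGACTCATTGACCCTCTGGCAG at 86856596 to 86856632. One intergenic element near Hfe2 (chromosome 3, 96489001 to 96489650, log2 5.85) carried both the leading ISRE, in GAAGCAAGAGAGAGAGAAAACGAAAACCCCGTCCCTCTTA at 96489348 to 96489387, and the leading CRE, in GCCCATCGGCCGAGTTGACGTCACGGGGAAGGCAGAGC at 96489436 to 96489473. The negative element with a CTCF consensus was at the promoter of Itga9 (chromosome 9, 118606326 to 118607125, log2 -3.75), where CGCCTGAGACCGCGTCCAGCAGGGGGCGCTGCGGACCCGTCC lies at 118606607 to 118606648.

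Positive elements lay near more genes of the Th2, T-cell activation, T-cell receptor and regulatory T-cell lists than of random gene sets. All 30 genes of the Th2 list had at least 1 positive element within 50 kb of their start, against 51.3% in random gene sets matched on gene density (permutation, adjusted p = 0.0017, from the smallest p the random sets can give). The strongest by q-value were near Gfi1 (log2 2.47), a transcriptional repressor that promotes Th2 cell expansion, the chemokine receptor genes Ccr8 (2.74) and Ccr3 (1.96), and Maf (2.58), which activates Il4. The T-cell activation list had positive elements at 26 of 29 genes (permutation, adjusted p = 0.0017), led by Bcl2a1b (3.78, at its promoter), Fosl1 (2.22), Nr4a3 (2.28) and Junb (2.71). Of the T-cell receptor and costimulation genes 22 of 26 had a positive element (permutation, adjusted p = 0.00227), with elements near Cd4 (3.47), Cd2 (2.56) and Fyb (2.01). The regulatory T-cell list had 13 of 15 (permutation, adjusted p = 0.0253), with elements in Foxp3 (2.75) and near Ebi3 (2.96), Il2ra (1.94) and Tnfrsf9 (2.81).

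The interferon and p53 programmes stood out as well. All 23 genes of the type I interferon response list had a positive element within 50 kb (permutation, adjusted p = 0.0017), and the elements of Ifit1 (log2 3.70), Ifih1 (3.56), Zbp1 (3.48) and Oasl2 (3.08) lay at promoters and each carried an ISRE. In a comparison chosen after the values were seen, 58% of the 50 positive elements near these genes had an ISRE, against 15.4% of other positive elements (Fisher's exact test, adjusted p = 5.23e-11). This was also the list with the highest positive share past the threshold, at 50 positive and 5 negative elements (odds ratio 3.99, Fisher's exact test, adjusted p = 0.00684). Among the p53 targets 15 of 16 had a positive element (permutation, adjusted p = 0.0017), including Bbc3 (2.91), Zmat3 (3.06), Cdkn1a (2.94) and Trp53inp1 (4.51), and p53 sites were in 5 of the 39 positive elements near them (12.8% against 1.77%, Fisher's exact test, adjusted p = 0.00221). Of the 7 such pairs of list and site, 4 did not pass. In positive elements near Th2 genes, GATA sites were in 21.1% against 19.4% elsewhere (Fisher's exact test, adjusted p = 0.763), STAT6 sites in 18.3% against 14.1% (Fisher's exact test, adjusted p = 0.429) and AP-1 sites in 35.2% of both (Fisher's exact test, adjusted p = 1). Near T-cell activation genes, AP-1 sites were in 26.4% against 35.2% (Fisher's exact test, adjusted p = 0.240).

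The Th1, Th17, interleukin-2 and STAT5, and naive and memory lists did not pass the threshold. Positive elements were near 15 of 20 Th1 genes (permutation, adjusted p = 0.0947), among them Tbx21 (2.46), Il12rb2 (2.23) and Gzmb (1.71). They were near 13 of 16 Th17 genes (permutation, adjusted p = 0.0535), with Stat3 at 1.98, Il22 at 6.24 and Il17a at 2.03. The Il22 fold is among the 100 largest positive ones, of which 71 had another near-identical match in the genome. Whether the Il22 element has such a match is not given here. The interleukin-2 and STAT5 targets had 14 of 17 (permutation, adjusted p = 0.0839), with Socs3 at 2.46 and Cish at 3.52, and STAT sites were in 39.3% of the positive elements near them against 23.4% elsewhere (Fisher's exact test, adjusted p = 0.0242). Naive and memory T-cell genes had 10 of 13 (permutation, adjusted p = 0.0947), with Il7r at 2.07. Each of these 4 lists passed under at least 1 alternative setting: all 4 at 100 kb and with the nearest start alone, the interleukin-2 and STAT5 list also at a q-value below 0.001, an absolute log2 fold of at least 1 and 10 kb, and the Th17 list also at a q-value below 0.001 and without duplicated elements. With the nearest start alone, the naive and memory list also had more negative elements than random sets. No difference of the Th2 list from these lists was tested.

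None of the 5 lists of other cell types passed the permutation test for positive elements. Positive elements were near 8 of 15 B-cell genes (Vpreb3, 2.55), 10 of 18 myeloid genes (Cx3cr1, 2.74, and Fcgr1, 2.96), 8 of 20 neuronal genes (Slc17a6, 2.09), 10 of 19 liver genes (Fga, 2.38) and 6 of 16 muscle genes (Mb, 2.42), the muscle share differing from random sets by -15.5 points, and the lowest permutation adjusted p among these 5 lists was 0.652. Cell-cycle genes had 15 of 26 (permutation, adjusted p = 0.898), with elements near Ccne1 (4.88) and Tyms (4.87). Ribosomal protein genes had positive elements at 29 of 42 (permutation, adjusted p = 0.0947), and were the one list with more negative elements than random sets, at 28 of 42 genes against 38.9% (permutation, adjusted p = 0.00227). They held 60 positive and 47 negative elements (odds ratio 0.506, Fisher's exact test, adjusted p = 0.00684), and the muscle list 6 and 10 (odds ratio 0.239, Fisher's exact test, adjusted p = 0.0267). Within 1000 bp of their own start, 5 of the 42 ribosomal genes had a negative element (11.9%), against 15.4% of other genes. A positive element was there at 8 of the 42. Neither share passed the threshold (Fisher's exact tests, adjusted p = 0.865 and 0.112), and both tests were chosen after the values were seen. The excess of negative elements within 50 kb was thus not seen at the ribosomal genes' own promoters. The Th2 list, with 71 positive and 19 negative elements, did not differ from all other elements in this share (Fisher's exact test, adjusted p = 0.274).

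Of the list calls, those of the Th2, interferon and T-cell activation lists held at every alternative run. The T-cell receptor call was lost at an absolute log2 fold of at least 1 and at 100 kb, the p53 call at 100 kb, the regulatory T-cell call at an absolute log2 fold of at least 1 and without duplicated elements, and the ribosomal call at a q-value below 0.001, an absolute log2 fold of at least 1, a 10 kb window and the nearest start alone. The excess over random sets, 48.7 points for the Th2 and for the interferon list, was 31.3 points for the Th2 list at 10 kb, and 30.5 and 30.7 points at 100 kb, and that of the p53 list went from 45.6 to 70.2 points at 10 kb and 27.5 points at 100 kb. The interferon odds ratio was 12.5 at a q-value below 0.001, 8.71 at an absolute log2 fold of at least 1 and 2.43 at 100 kb. The Fisher calls of the interferon and ribosomal lists were lost at 10 kb, and that of the muscle list in most alternatives. Some examples are not specific to their list or gene. The element near Ccr8 lies nearer to Cx3cr1 of the myeloid list, and that near Trp53inp1 nearer to Ccne2 of the cell-cycle list. Within 50 kb of Cd4 there were 1 positive and 4 negative elements, of Socs3 1 and 3, and of Ebi3 and of Zmat3 1 and 2. The positions of the tested regions that did not reach the table are not known here, so random gene sets stand in for them.

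**Figure D4:**
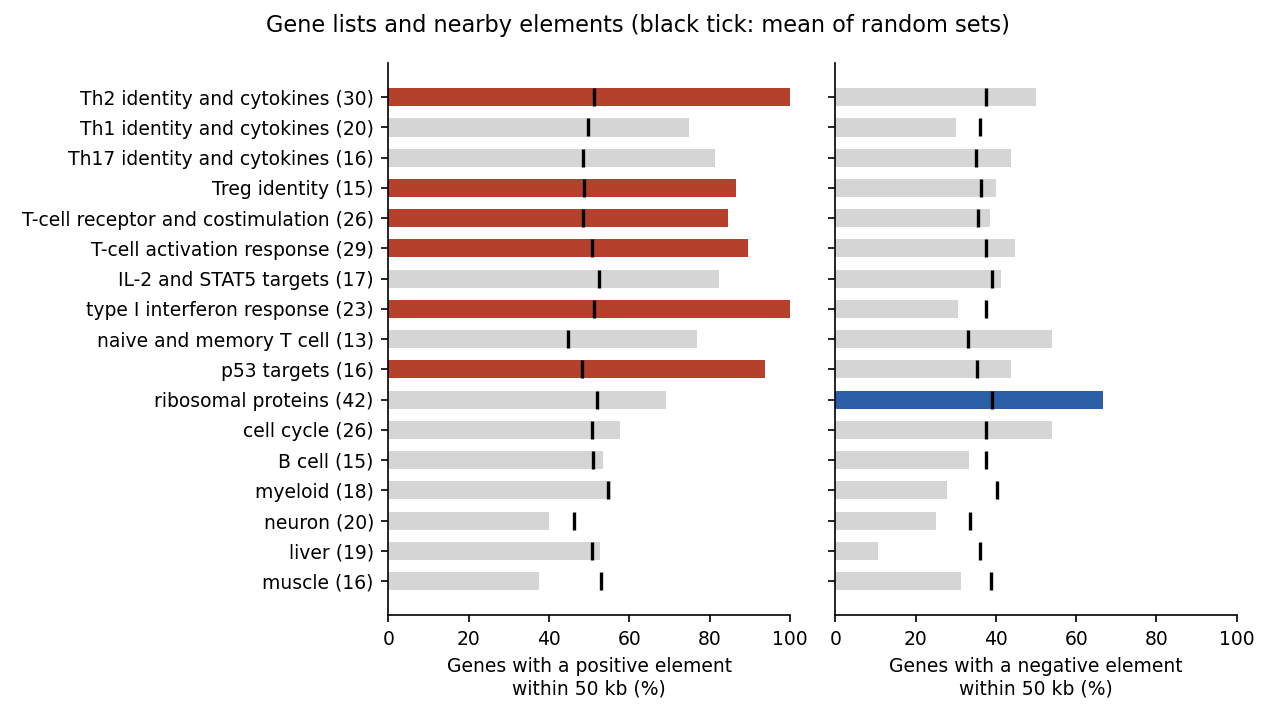
Percentage of the genes of each fixed list (number of genes in parentheses) with a positive element (left) or a negative element (right) within 50 kb of the start. Coloured bars passed the permutation test after adjustment, grey bars did not, and black ticks are the mean of random gene sets; the Th2 and interferon lists reach 100% for positive elements against about 51.3% in random sets.

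At the Th2 cytokine locus on chromosome 11, which holds Il4, Il13, Rad50 and Il5, 7 positive elements and 1 negative element lay in the stretch drawn in the map of this locus. The largest log2 fold, 2.00, was at 53626776 to 53627325, between Il4 and Il13, in an element with a GATA consensus. An element with AP-1 and GATA sites inside a Rad50 intron (53656701 to 53657200), the gene whose 3' part holds the known control region of this locus, had a log2 fold of 1.64. An intronic element of Il4 (53614751 to 53614975) was at 1.00, and an element between Rad50 and Il5 (53713676 to 53713950) at 1.18. The negative element (53636101 to 53636650, log2 -1.17) lay 1673 bp from the start of Il13. At the Ifit locus on chromosome 19, a cluster of interferon-induced genes, 8 elements were positive and 1 was negative. The Ifit3 promoter element (34583051 to 34583500, log2 3.86) and the Ifit3b promoter element (34607326 to 34607950, log2 2.67) both carried an ISRE, and each had 1 other near-identical match in the genome. The positive elements starting at 34588076, 34599351 and 34612526 also had 1 such match each. The Ifit2 promoter element was negative (34550451 to 34551150, log2 -0.86).

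**Figure D5:**
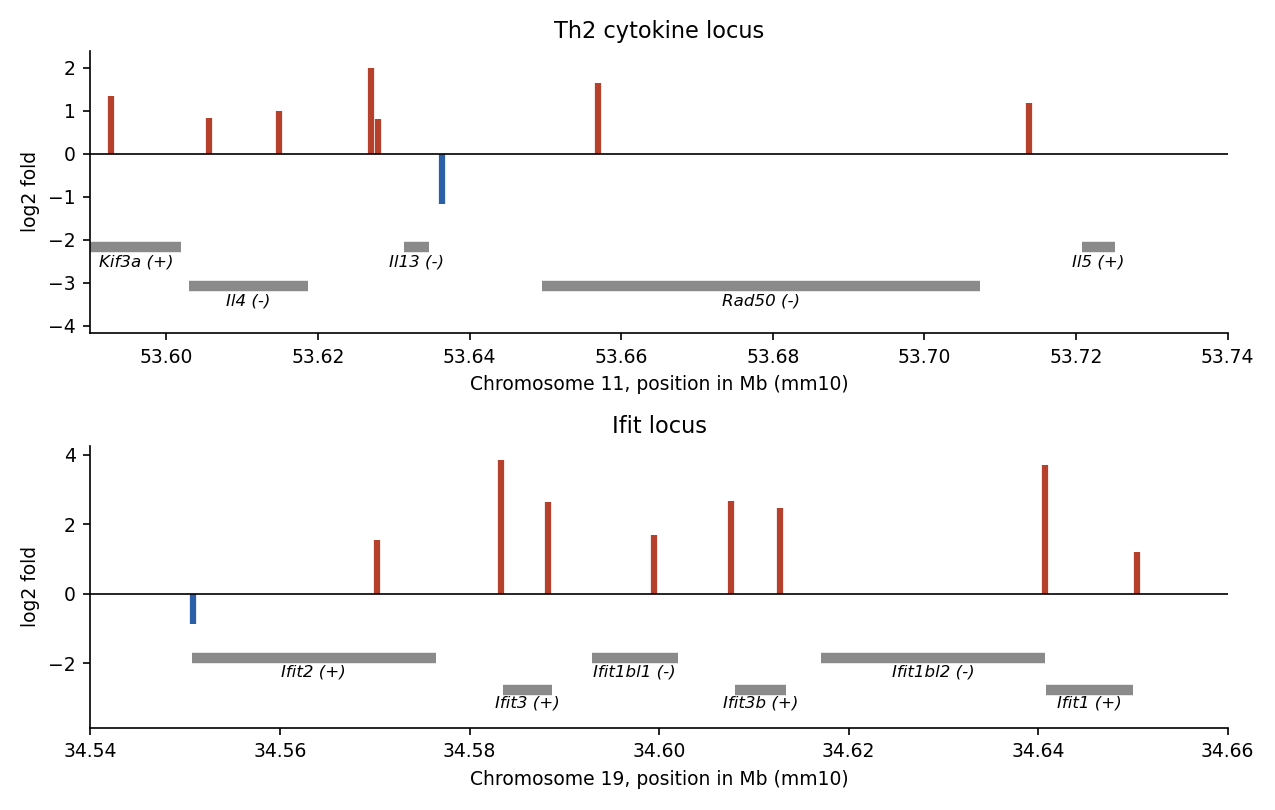
Log2 fold (vertical axis) of each element by position in Mb on the mm10 assembly at the Th2 cytokine locus and the Ifit locus, with positive elements in red, negative elements in blue and protein-coding genes as grey bars with their strand. Folds reach 2.00 in the upper and 3.86 in the lower map.

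Elements of the same direction lay near each other more often than when directions were reshuffled. An element of the same direction lay within 10 kb of 23.2% of the elements, against 19.5% when directions were reshuffled within chromosomes (permutation p = 0.002, the smallest possible). The difference of 3.65 points was 2.29 points within 2 kb and 1.57 points within 50 kb. By chromosome, the density of elements ran from 2.51 per Mb on X to 10.3 per Mb on chromosome 11 among the autosomes and X, and the positive share from 66.1% on chromosome 4 to 78.4% on X. The Y chromosome held 6 elements, all positive.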

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

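The patterns below were noticed in the data, and their tests and bounds were set before those tests were run; the count of related elements as 1, the shares by GC range and the bins of GC content and CpG density together were chosen after the results were seen.

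The table held 17 elements on unplaced or unlocalised scaffolds, which the comparisons of sequence and genes do not use. They are raised here because they are a signal in data outside those comparisons. Of these, 13 were positive and 4 negative, on 7 scaffolds, with log2 folds from -2.65 to 2.81.

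Negative folds lay at promoters, with an unadjusted odds ratio of 17.9 (16.6 to 19.4) of a promoter element being negative. The common odds ratio was 11.99 (10.9 to 13.1) within bins of element width, 2.11 (1.85 to 2.41) within bins of GC content and 1.87 (1.63 to 2.14) within bins of CpG density. Each lower bound lies above the 1.5 set as the limit for a trend that explains the whole pattern, so each alone is argued against as the whole cause, but most of the excess goes with base composition, and within bins of GC content and CpG density together the value was 1.79 (1.54 to 2.08). A bias of amplification or sequencing with GC content between output and input libraries may therefore account for much of it, and stays open because no per-library values or input are analysed here. No biological explanation was tested, since the study has 1 group.

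Positive elements with a p53 consensus had larger folds, by 1.41 on the log2 scale (bootstrap 95% interval 1.26 to 1.56, 237 elements with the site). The difference was 1.15 (0.844 to 1.38) among elements with under 10% repeat-masked sequence, of which 88 had the site. This argues against masked repeats as the whole cause, and cannot speak for repeats that the masking misses. It was 1.37 (1.25 to 1.52) among elements with no other near-identical match, of which 224 had the site. This argues against near-identical copies as the whole cause. Relatives of lower identity stayed in this set, so it cannot tell whether reads shared over shorter stretches play a part. After matching on width and GC content the difference was 1.41 (1.26 to 1.56). Many of the elements with the site are related in sequence, up to 83 of the 237 in 1 group, and with 1 value per group the difference was 1.17 (0.952 to 1.31, 152 groups), and 1.11 (0.813 to 1.36, 85 groups) under 10% masked, so counting related elements as separate accounts for part of it at most. No biological explanation was tested, since the study has 1 group and neither p53 activity nor its binding was measured.

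The largest positive folds lay in duplicated sequence. Of the 100 largest, 71 had another near-identical match, against 4.90% of other positive elements (odds ratio 47.5, 30.1 to 76.4, Fisher's exact test, p = 1.05e-67). Narrow elements as the cause are argued against, since the common odds ratio within bins of width was 35.4 (21.6 to 57.8). The first value is the pattern itself, so it decides nothing between reads shared between copies and activity of the duplicated sequences, and both stay open. The size of a fold above a log2 of 5.20, the smallest of the 100, is therefore uncertain where a copy exists.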

How the results depend on the processing

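The settings with a q-value below 0.001, with thinned lists, without duplicated elements and outside promoters were chosen after seeing the data. The planned q-value below 0.01 removes nothing, because all elements already pass it, and the planned filter on input depth and the fits without 1 replicate were not run, because the table has no such columns. No paired analysis was possible because the study has 1 group and no values per library. Depth could not be examined at all.

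The promoter, intron and intergenic contrasts, the GC and CpG contrasts, the width correlations and the clustering kept their direction and stayed past the threshold at every alternative run for them. Of the values that answer a comparison, 90 kept their direction and side of the threshold (for counts, stayed within 1.5 times; for shares, within their interval) and 16 did not. Some of the 90 moved in size, as the class odds ratios did at a q-value below 0.001, and negative elements fell in number to 3714 at an absolute log2 fold of at least 1. At a q-value below 0.001 there were 8483 positive and 2708 negative elements, 75.8% positive, 1 consensus site higher in negative elements in place of 2, and 0 lists with more negative elements in place of 1. At an absolute log2 fold of at least 1 there were 8565 positive elements, 69.8% of all, and 0 such lists. The positive share was 72.8% with 1 element per 5 kb cluster and 70.4% without duplicated elements. Matched on GC content and length, and outside promoters, 1 consensus site was higher in negative elements. A window of 10 kb left 0 lists with more negative elements, and the nearest start alone gave 10 lists with more positive elements in place of 6. The exon odds ratio moved from 0.875 to 0.558 with promoters of 500 bp, past the threshold, and reversed to 1.28 when any overlap was counted. The filters and windows themselves change how many elements are counted; for the other changes the cause was not tested.

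Among single consensus sites and gene lists, 338 values kept their call or their lack of one (some that never passed changed sign), 32 lost their call, 14 gained one (all of them gene lists) and 1 reversed. The reversed one was the adjusted odds ratio of SP/KLF, 0.770 over all elements and 1.16 outside promoters, where it did not pass the threshold. Of the 11 named consensus sites 7 were still called at a q-value below 0.001. Calls of AP-1, the STAT site, ISRE and p53 were kept in all settings run.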

Other observations

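The tests in this part were all chosen after the results above were seen. Elements at the genes' own promoters set 2 lists apart. Of the 23 interferon response genes, 21 had a positive element within 1000 bp of their start (91.3%), against 7.20% of other protein-coding genes (odds ratio 135, Fisher's exact test, adjusted p = 8.53e-21). These included Isg15, a ubiquitin-like antiviral protein (log2 3.25), Irf9 (3.34) and Irf7 (2.36), which transmit the interferon signal, Usp18 (2.19), Cxcl10 (1.93), Stat2 (1.62), Oasl1 (2.95) and Ifi44 (3.08), and at the low end Ddx58 (0.71) and Gbp2 (0.67). Of the 16 p53 targets, 12 had a positive promoter element (75%, odds ratio 38.5, Fisher's exact test, adjusted p = 5.05e-10), among them Cdkn1a (2.94), which arrests the cell cycle, the cell death genes Bbc3 (2.91) and Bax (2.01), Eda2r (2.63), Ccng1 (2.37) and Mdm2 (1.34), the negative regulator of p53. Among these named promoter elements, that of Ccng1 carried the p53 consensus, and those of Cdkn1a, Bbc3, Bax, Eda2r and Mdm2 did not. Of other p53 targets, the promoter elements of Plk2 and Aen carried it, and those of Btg2, Trp53inp1 and Sesn2 did not. The search asked for an exact match, so an element without one may still hold a p53 site. In the Th2 list, 1 of the 30 genes had a positive promoter element, although all 30 had one within 50 kb. That promoter share (3.33%) did not differ past the threshold from other genes (7.29%, Fisher's exact test, adjusted p = 0.865). No difference between lists was tested. None of the other 32 tests of promoters (17 lists, both directions) passed the adjusted threshold. Whether the introduction of DNA into the cells turned on either programme was not tested.

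Many of the elements with the largest folds were related to each other in sequence. Each of the 11630 positive elements of at least 200 bp was aligned to all of the others. Of the 688 with a log2 fold of 3 or more, 59.2% had a related element, against 26.0% of those from 2 to under 3, 13.5% from 1 to under 2, and 6.25% under 1. No p is given, since related elements are not independent. Within the 688, 361 were related to another of them and fell into 56 groups linked by alignment, and the largest group held 105 elements on 20 chromosomes with a median log2 fold of 4.09 and a median repeat-masked share of 74%. Its commonest consensus sites were NFY, in 44.8% of members, and p53, in 21.9%. Its largest fold was the element nearest to Zfp53. The second group held 67 elements on 20 chromosomes, with a median log2 fold of 4.08, a median masked share of 73.3% and no near-identical match for any member, and its commonest consensus site was in 14.9% of them. A group of 20 elements on 15 chromosomes had a p53 consensus in 85% of its members, and its largest fold, 4.73, was near Kctd12 (chromosome 14, 102731726 to 102732075). A group of 15 had RUNX sites in 93.3%, and a group of 14, which holds the element near Hfe2, had FOX sites in 92.9%, YY1 sites in 78.6% and CRE sites in 64.3%. The groups of 20 and 14 held no element with a near-identical match elsewhere. A group of 10 near Gm14399 lay on 1 chromosome, and each of its members had such a match.

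The direction of the fold is not given in the sources used here and stays an assumption. Of the 243 elements with the consensus of p53, an activator of transcription, 97.5% were positive (exact 95% interval 94.7 to 99.1). This share restates the count that prompted the comparison, so it decides nothing about the direction.

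In all, 3 positive elements matched the mitochondrial genome. They were nearest to Col19a1 (log2 6.03), Ccnh (chromosome 13, 85127026 to 85127250, log2 4.28) and Myo3a (chromosome 2, 22589551 to 22589850, log2 3.95). No negative element did.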
